A study of Mus musculus with 3 samples.

How the data were processed

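The series is labelled as 3 RNA-seq libraries of mouse distal colon, wild type and at steady state. Per the labels' protocols, polyadenylated RNA was extracted with TRIzol and made into libraries with an Illumina TruSeq RNA kit. The replicate numbers come from the sample titles. The labels name the strain JAX, which is a supplier's name, and do not say whether the replicates came from separate animals. They form 1 group, so no test between conditions and no pairing of samples applies.

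Each deposited file is an isoform table, 1 per labelled library, that the authors made with Cufflinks, whose column names the file headers carry. FPKM values, fragments scaled to isoform length and to mapped fragments, were deposited by the authors with a lower and an upper 95% confidence bound, per the file headers. The mean read coverage of each isoform, a signal not scaled to the library, is also given per the file headers and was used only to compare depth. TopHat2 2.1.1, Bowtie2 2.3.4.3 and Cufflinks 2.2.1 are named in the submitters' processing notes, with no order or settings. The strandedness of the counting, the treatment of reads that match several places and any trimming are not given in the sources used here. All 34535 isoforms (29596 coding NM and 4939 non-coding NR entries of RefSeq) carry the status OK, and none lies on the mitochondrial chromosome, so mitochondrially encoded genes are not analysed here.

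The submitters' processing notes name GRCm39 as the build, but the positions in the files are those of GRCm38. Of 23037 symbols compared with RefSeq genes on GRCm38.p6, 14226 (61.8%) had the same start base and 22558 (97.9%) a start or an end within 1000 bases. Positions are therefore printed as GRCm38.

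Isoform FPKM were summed per gene symbol and chromosome, which gave 24406 genes from 24346 symbols; gene lists used the sum per symbol. Nothing was rescaled. The files hold no counts, but the depth can be recovered: the upper bound less the FPKM is read as 2 standard errors, and the squared standard error over the FPKM is then the FPKM worth of 1 fragment. In single-isoform genes longer than 800 bases with up to 30 such fragments, 64.2% of the values in replicate 1, 64.2% in replicate 2 and 64.3% in replicate 3 lay within 0.01 of a whole number. The Theil-Sen slope of fragments per unit of FPKM on length in these genes gave 3.78e+06, 3.79e+06 and 1.24e+06 mapped fragments, 8.81e+06 in all, of which the listed isoforms held 73.5%. These fragments were not rounded to counts, since the remaining values tested were not whole. The test between files uses them as sampling variances, the FPKM worth of 1 fragment times the gene's weighted mean. The limit for a gene listed at 0 is 3 fragments over the 3 files together, at a shortened length of its shortest isoform. The length taken off is the mean over the files of the length at which the fitted line reached 0, which was 191 to 201 bases. Limits and intervals cover counting error only.

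The spread between files was tested in genes with 1 isoform and a mean of at least 1 FPKM. After scaling to a common median ratio, the 3 values of a gene were compared with their weighted mean by a chi-square test with the sampling variances above, with Benjamini-Hochberg adjustment at 0.05. The ratio reported is the median over genes of the variance between files over the sampling variance, with a bootstrap of 1000 draws over genes. The procedure was tested on simulated data for the same 8782 genes, with Poisson counts at the sampling variances of the bounds. With no change, the median ratio was 0.684 and 0 genes were called. With 100 genes changed 1.5-fold and 100 changed 2-fold in 1 file, 43.0% and 79.0% were recovered and 9 unchanged genes were called. A simulated spread of 20% between files, a size chosen after the observed ratio was seen, gave a ratio of 2.34 and 2990 calls. Because the files differed by about as much as sampling noise, they were counted as 1 sample, as the design had laid down, and with nothing that says they came from separate animals no p-value here measures a spread between animals.

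For the gene lists, 51 lists of cell types, functions, other organs and Hox groups were fixed beforehand. Of these, 50 had at least 1 gene with values, and the list of mitochondrially encoded proteins had none. The percentile of a list's median was taken among 10000 random lists of the same size from symbols with a mean above 0, with a seed of 20 plus the list size. Lists of other genes of liver, Paneth cells and small intestine enterocytes, and of kidney, lung, testis, heart, brain and stomach, were written after the levels of the fixed lists had been seen and are used only in the closing observations. Isoform shares are percentages of a gene's summed FPKM in each file.

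The genes named were chosen by a rule fixed beforehand. It takes the 20 genes of highest mean FPKM outside the ribosomal protein families, the 4 highest members of each list, up to 3 members in list order that lie under 1 FPKM in every file, and every Hox gene at 1 FPKM or more. It also takes the 10 highest genes at 10 FPKM or more with at least 2 isoforms of 20% or more in every file, every gene of a fixed list of 27 isoform genes, and the 10 genes at 10 FPKM or more with the smallest p between files. Some genes that the rule takes are not reported here. Near-identical copies were sought with BLAST+ 2.17.0 (megablast) in the GENCODE M21 transcripts of GRCm38, as a match of at least 100 bases at 97% identity or more to a transcript of another gene, overlapping genes included. Such a match was found for 8 of the 20 highest genes, 19 of which had a sequence, and for 46 of 169 genes that lead a list. After the levels had been seen, the search was extended to the 22 Hox genes with a mean of 1 FPKM or more, 9 of which had a match, and to 19 genes that lead the later lists, 6 of which had one. Other genes were not searched, apart from those of the isoform and file comparisons.

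Alternatives covered the thresholds, rescaling each library to a common sum (TPM), the highest isoform in place of the sum, the authors' status, the background and summary of the list percentiles, the pseudocount, the genes tested between files, the dominance threshold and leaving out each replicate in turn. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.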

Results

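The series profiled polyadenylated RNA of the distal colon of wild-type mice at 8 weeks of age and at steady state. All 3 labelled libraries carry the same tissue, genotype, strain and treatment labels and form 1 group, so the series holds no contrast between conditions. What it measures is the level of each transcript in this tissue, and the comparisons given here are between gene groups, between the isoforms of a gene and between the 3 files. The depth recovered from the deposited confidence bounds was 3.78e+06 mapped fragments in replicate 1, 3.79e+06 in replicate 2 and 1.24e+06 in replicate 3. In genes with 1 isoform and a mean of at least 1 FPKM, the 3 files differed by about as much as sampling noise, and they were counted as 1 sample. Each value is therefore the mean FPKM over the 3 files ± their SD, a measurement error of that sample which holds no estimate of the spread between animals. For a gene listed at 0 in every file, the limit given is the FPKM that 3 fragments over the 3 files together would make, and it covers counting error only. Positions are on GRCm38, counted from 1.

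Of 24406 genes, 11815 stood at or above 1 FPKM in every file, and 12601, 12643 and 12539 did so in replicates 1, 2 and 3. Means of 100 FPKM or more were reached by 631 genes and means of 1000 FPKM or more by 57. The 100 highest genes held 30.6% ± 0.0731 of the summed FPKM.

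Apart from ribosomal protein genes, the most abundant transcript was that of Lypd8, a secreted protein of the colonic surface that keeps flagellated bacteria away from the epithelium, at 8567 ± 57.7 FPKM (chromosome 11, 58379032 to 58390541), or 2.00% of the summed FPKM. Zg16, a lectin of goblet cell mucus, followed the translation factor Eef1a1 (3748 ± 56.4 FPKM) at 3151 ± 119 FPKM (chromosome 7, 127050156 to 127051977), and the goblet cell trefoil peptide Tff3 reached 2276 ± 62.1 FPKM. Epithelial cytoskeleton and lectin genes were also among the 20 highest: Krt8 at 1682 ± 23.4 FPKM, Lgals4 at 1653 ± 43.6 FPKM and Krt19 at 1401 ± 12.3 FPKM. The other places included Tpt1 (2959 FPKM), the ferritin heavy chain Fth1 (1920 FPKM), the cornified envelope genes Sprr2a1 (1840 FPKM), Sprr2a2 (1791 FPKM) and Sprr2a3 (1771 FPKM), Actb (1682 FPKM), Crip1 (1596 FPKM), S100a6 (1522 FPKM), B2m (1430 FPKM), Actg1 (1417 FPKM) and Prdx6 (1409 FPKM). Rn45s, the ribosomal RNA precursor, came at 1396 FPKM in spite of the polyadenylated selection and took 0.787% of the mapped fragments. The levels of Sprr2a1, Sprr2a2, Sprr2a3, Eef1a1, Tpt1, Krt8 and Actg1 are uncertain, because each has a transcript of another gene that matches it over at least 100 bases at 97% identity or more.

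Gene lists fixed before the data were examined were ranked by their median level among 10000 random lists of the same size, drawn from the 17060 symbols above 0. The percentile describes this sample and is not a test, since genes are not replicates. The RNA is that of a tissue with many cell types. A gene of a list, its highest members included, may therefore come from cells other than those the list is named for. Of the 50 lists with values, 17 lay at or above the 95th percentile and 15 at or below the 5th.

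The median of 16 general epithelial genes was 279 ± 7.63 FPKM, above all 10000 random lists, with Epcam, the epithelial adhesion molecule, at 794 ± 15.1 FPKM. Absorptive colonocyte genes had a median of 70.7 ± 2.01 FPKM, also above all random lists, led by the carbonic anhydrases Car4 (817 ± 13.5 FPKM) and Car1 (454 ± 9.11 FPKM), Ceacam1 (600 ± 10.6 FPKM) and the guanylin gene Guca2a (334 ± 11.7 FPKM). The levels of Car1 and Ceacam1 are uncertain, since each shares a stretch with a near-identical transcript of another gene. Of their 15 members, 13 had a mean of 1 FPKM or more, while Slc9a3, the apical sodium-proton exchanger, stood at 0.227 ± 0.197 FPKM and the retinol dehydrogenase Dhrs9 at 0.234 ± 0.0599 FPKM. Goblet cell genes had a median of 238 ± 3.44 FPKM, above all random lists, and 14 of 15 reached 1 FPKM. Beside Zg16 and Tff3, Klk1 stood at 888 ± 23.3 FPKM and Clca1 at 880 ± 4.47 FPKM.

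Tight junction, ion transport and short-chain fatty acid genes also lay in the upper range. The median of 20 tight junction genes was 25.6 ± 0.692 FPKM (99.97th percentile), with the claudins Cldn7 at 428 ± 10 FPKM, Cldn3 at 291 ± 4.51 FPKM and Cldn8 at 92.8 ± 1.67 FPKM and the adhesion molecule F11r at 86.7 ± 1.02 FPKM. The stomach and lung claudin Cldn18 was listed at 0, with a limit of 0.132 FPKM. Ion and water transport genes had a median of 24.8 ± 0.0761 FPKM (99.97th percentile). The sodium pump subunit Atp1b1 (742 ± 1.01 FPKM), the chloride-bicarbonate exchanger Slc26a3 (215 ± 1.56 FPKM) and Hsd11b2, which protects the mineralocorticoid receptor from glucocorticoids (187 ± 12 FPKM), were among the highest. The water channel Aqp3 was listed at 0, with a limit of 0.217 FPKM. Genes of short-chain fatty acid uptake and oxidation had a median of 40.9 ± 1.54 FPKM (99.97th percentile), with Hadh at 126 ± 4.67 FPKM, the monocarboxylate transporters Slc16a1 at 99.0 ± 2.03 FPKM and Slc5a8 at 85.4 ± 1.32 FPKM, and Acadm at 58.8 ± 4.57 FPKM. Of their receptors, Ffar3 (0.485 ± 0.107 FPKM) and Hcar2 (0.346 ± 0.373 FPKM) stayed under 1 FPKM in every file. The other 10 of the 12 genes, the receptor Ffar2 among them, had a mean of 1 FPKM or more. Mucins divided sharply: Muc13 stood at 843 ± 29.2 FPKM and Muc2 at 238 ± 3.44 FPKM, Muc1 at 5.88 ± 0.631 FPKM and Muc4 at 4.36 ± 0.602 FPKM. The gel-forming mucins Muc5ac and Muc5b were listed at 0, with limits of 0.0410 and 0.0231 FPKM, and Muc6 stood at 0.0110 ± 0.0191 FPKM. The median of the 9 mucins was 0.808 ± 0.0942 FPKM (3.63rd percentile, or the 48.6th by their mean log2(FPKM + 1)).

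Crypt and secretory cell genes covered a wider range. All 12 stem cell and crypt base genes reached 1 FPKM in every file, with a median of 8.16 ± 0.433 FPKM (80th percentile). They lay at the 95.1st percentile by their mean log2(FPKM + 1) and at the 45.1st against genes at or above 1 FPKM alone. Reg4, a product of the deep crypt secretory cells of the colon, stood at 223 ± 7.14 FPKM, the crypt transcription factor Sox9 at 33.6 ± 1.38 FPKM, Lrig1 at 22.7 ± 2.26 FPKM and Smoc2 at 14.3 ± 1.16 FPKM. The 14 proliferation genes all reached 1 FPKM as well (median 14.1 ± 0.370 FPKM, 97.7th percentile), with Ube2c at 46.5 ± 7.66 FPKM and Pcna, uncertain for a pseudogene copy, at 75 ± 5.87 FPKM. Enteroendocrine genes had a median of 3.12 ± 0.735 FPKM (26.4th percentile) but included the hormone genes Pyy at 231 ± 13.7 FPKM, Insl5 at 115 ± 13.9 FPKM and Gcg, the precursor of glucagon-like peptides, at 28.3 ± 3.02 FPKM, with the granule protein Chgb at 30 ± 2.15 FPKM. Cck, a hormone of the upper intestine, stood at 0.168 ± 0.290 FPKM. Tuft cell genes had a median of 0.680 ± 0.246 FPKM (under the 5th percentile). Ptgs1 stood at 9.67 ± 0.711 FPKM and Dclk1 at 3.59 ± 1.23 FPKM, while Trpm5 stood at 0.355 ± 0.417 FPKM, Pou2f3 at 0.564 ± 0.197 FPKM, and Il25 was listed at 0, with a limit of 0.392 FPKM.

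Smooth muscle genes had a median of 187 ± 3.54 FPKM, above all random lists, and all 16 reached 1 FPKM in every file. They were led by Tagln (754 ± 18.9 FPKM), the smooth muscle actins Actg2 (581 ± 43.3 FPKM) and Acta2 (554 ± 6.60 FPKM), and the myosin light chain Myl9 (492 ± 16.9 FPKM). The 14 fibroblast and matrix genes (median 75.2 ± 0.894 FPKM, above all random lists) included Dcn at 188 ± 2.14 FPKM, Postn at 164 ± 4.88 FPKM and Col3a1 at 113 ± 2.19 FPKM. Among stromal niche signals (median 4.22 ± 0.587 FPKM, 40.8th percentile), the bone morphogenetic proteins Bmp2 (43.9 ± 2.69 FPKM) and Bmp4 (19.3 ± 1.2 FPKM) and the antagonist Grem1 (9.41 ± 2.05 FPKM) were among the highest. Interstitial cell of Cajal genes lay at the 62.9th percentile, with the pacemaker chloride channel Ano1 at 51.6 ± 1.54 FPKM and Kit at 8.99 ± 0.532 FPKM. Pericyte genes lay at the 52.8th percentile (Rgs5 at 34.8 ± 2.28 FPKM). Lymphatic endothelium genes lay at the 55.2nd (Ccl21a at 35.3 ± 4.76 FPKM, uncertain for near-identical copies, and Lyve1 at 11.7 ± 1.27 FPKM) and blood endothelium genes at the 27.1st (Plvap at 16.1 ± 1.57 FPKM). Enteric neuron genes lay at the 41.8th percentile, with the neuropeptides Vip at 36.0 ± 1.13 FPKM and Tac1 at 17.5 ± 4.49 FPKM, and 16 of 19 reached a mean of 1 FPKM. Enteric glia genes lay at the 23.0th, with Erbb3 at 34.0 ± 3.18 FPKM.

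T cell genes had a median of 0.512 ± 0.0279 FPKM (under the 5th percentile), with Cd3e at 2.65 ± 0.543 FPKM and Cd4 at 1.30 ± 0.179 FPKM. The T cell list was read without the receptor constant genes Trac, Trbc1 and Trbc2, and the plasma cell list without the immunoglobulin genes Igha, Igkc and Ighm, which are not analysed here. B cell genes had a median of 0.233 ± 0.0576 FPKM (also under the 5th percentile), with Cd79b at 2.48 ± 0.130 FPKM. Plasma cell genes had a median of 20.4 ± 1.51 FPKM (96.0th percentile), led by Jchain, the joining chain of secreted IgA, at 314 ± 10.3 FPKM and Xbp1 at 82.4 ± 5.92 FPKM. Macrophage genes lay at the 74.9th percentile, with Lyz2 at 125 ± 4.26 FPKM and the complement genes C1qa at 30.8 ± 2.39 FPKM and C1qc at 28.1 ± 1.84 FPKM. Dendritic cell genes also lay under the 5th percentile, although Irf8 stood at 14.8 ± 1.27 FPKM, and the median of the mast cell genes fell below all random lists, with Cma1 at 5.24 ± 1.78 FPKM. No neutrophil or eosinophil gene reached a mean of 1 FPKM. S100a8 and S100a9, the calprotectin subunits, were listed at 0, with limits of 1.72 and 1.04 FPKM.

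Antimicrobial and host defence genes had a median of 11.8 ± 1.16 FPKM (95.2nd percentile, and the 94.9th without replicate 2 and the 93.7th without replicate 3). After Lypd8 came the acute phase protein Saa1 at 1357 ± 117 FPKM, the IgA transporter Pigr at 933 ± 13.1 FPKM and Wfdc2 at 384 ± 19.7 FPKM. Nos2 stood at 0.138 ± 0.138 FPKM. MHC class II genes lay at the 99.99th percentile (median 75.9 ± 2.72 FPKM), with Cd74 at 387 ± 15.4 FPKM, H2-Aa at 199 ± 4.44 FPKM and H2-Ab1 at 140 ± 6.93 FPKM. Of the innate sensing genes (86.6th percentile), the inflammasome genes Il18 (111 ± 9.36 FPKM), Casp1 (68.0 ± 1.49 FPKM), Gsdmd (52.7 ± 2.56 FPKM) and Pycard (50.7 ± 1.73 FPKM) were highest. The endosomal receptors Tlr7 (0.611 ± 0.262 FPKM), Tlr8 (0.296 ± 0.050 FPKM) and Tlr9 (0.295 ± 0.170 FPKM) were under 1 FPKM in every file. Interferon response genes lay at the 92nd percentile, with Irf7 at 55.6 ± 1.51 FPKM and Oasl2 at 31.6 ± 5.21 FPKM. Of 18 inflammatory cytokines and chemokines, 9 were listed at 0 in every file and 2 reached a mean of 1 FPKM, Ptgs2 at 2.80 ± 0.155 FPKM and Cxcl10 at 2.36 ± 1.30 FPKM. Their median fell below all random lists. Il6 was listed at 0, with a limit of 0.382 FPKM, and Tnf stood at 0.118 ± 0.205 FPKM.

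Xenobiotic metabolism genes lay at the 98.8th percentile (median 15.2 ± 0.507 FPKM), with the sulfotransferase Sult1b1 at 81.7 ± 2.00 FPKM, the efflux pump Abcb1a at 64.9 ± 3.64 FPKM and Cyp2c55 at 58.8 ± 3.33 FPKM, while Cyp1a1 stood at 0.0717 ± 0.0621 FPKM. Bile acid handling genes lay at the 5.95th percentile, at the 3.27th without replicate 1, the 2.65th without replicate 2 and the 8.47th without replicate 3. By the mean log2(FPKM + 1) they lay at the 23.4th, and against all genes listed at the 45.3rd. The bile acid receptor Nr1h4 stood at 17.5 ± 0.944 FPKM and its ileal target Fgf15 at 0.0536 ± 0.0929 FPKM. Immediate early genes lay at the 98.7th percentile, with Fos at 71.9 ± 3.39 FPKM, Zfp36 at 56.9 ± 1.59 FPKM and Junb at 49.8 ± 1.46 FPKM. Clock genes lay at the 45.8th percentile, with Bhlhe40 at 50.1 ± 5.71 FPKM, the repressor Nr1d1 at 39.8 ± 1.97 FPKM and its target Arntl at 19.7 ± 2.95 FPKM. The hour of collection is not given in the sources used here. The median of the housekeeping genes lay above all random lists.

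Genes of other organs were listed to check for foreign tissue. Small intestine enterocyte and Paneth cell genes nevertheless lay at the 99.9th percentile (median 23.9 ± 1.73 FPKM), with the ileal bile acid binding protein Fabp6 at 95.6 ± 5.85 FPKM (chromosome 11, 43596040 to 43601562), the peptide transporter Slc15a1 at 85.3 ± 5.45 FPKM, the Paneth cell defensin Defa24 at 63.6 ± 11.3 FPKM and the glucose transporter Slc5a1 at 41.3 ± 1.96 FPKM. The lactase gene Lct (0.0440 ± 0.0441 FPKM) and the alkaline phosphatase gene Alpi (0.285 ± 0.0731 FPKM) stayed under 1 FPKM in every file, and Gata4, a transcription factor of the proximal intestine, was listed at 0, with a limit of 0.106 FPKM. Defa24 is uncertain for near-identical defensin copies. Liver genes lay at the 89.1st percentile, or the 98.9th by their mean log2(FPKM + 1), and all 7 reached 1 FPKM in every file: Alb stood at 129 ± 5.35 FPKM (chromosome 5, 90460889 to 90476603), Ttr at 60.7 ± 7.73 FPKM, Apoa2 at 60.0 ± 8.51 FPKM and Ahsg at 12.6 ± 0.693 FPKM.

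**Figure D1:**
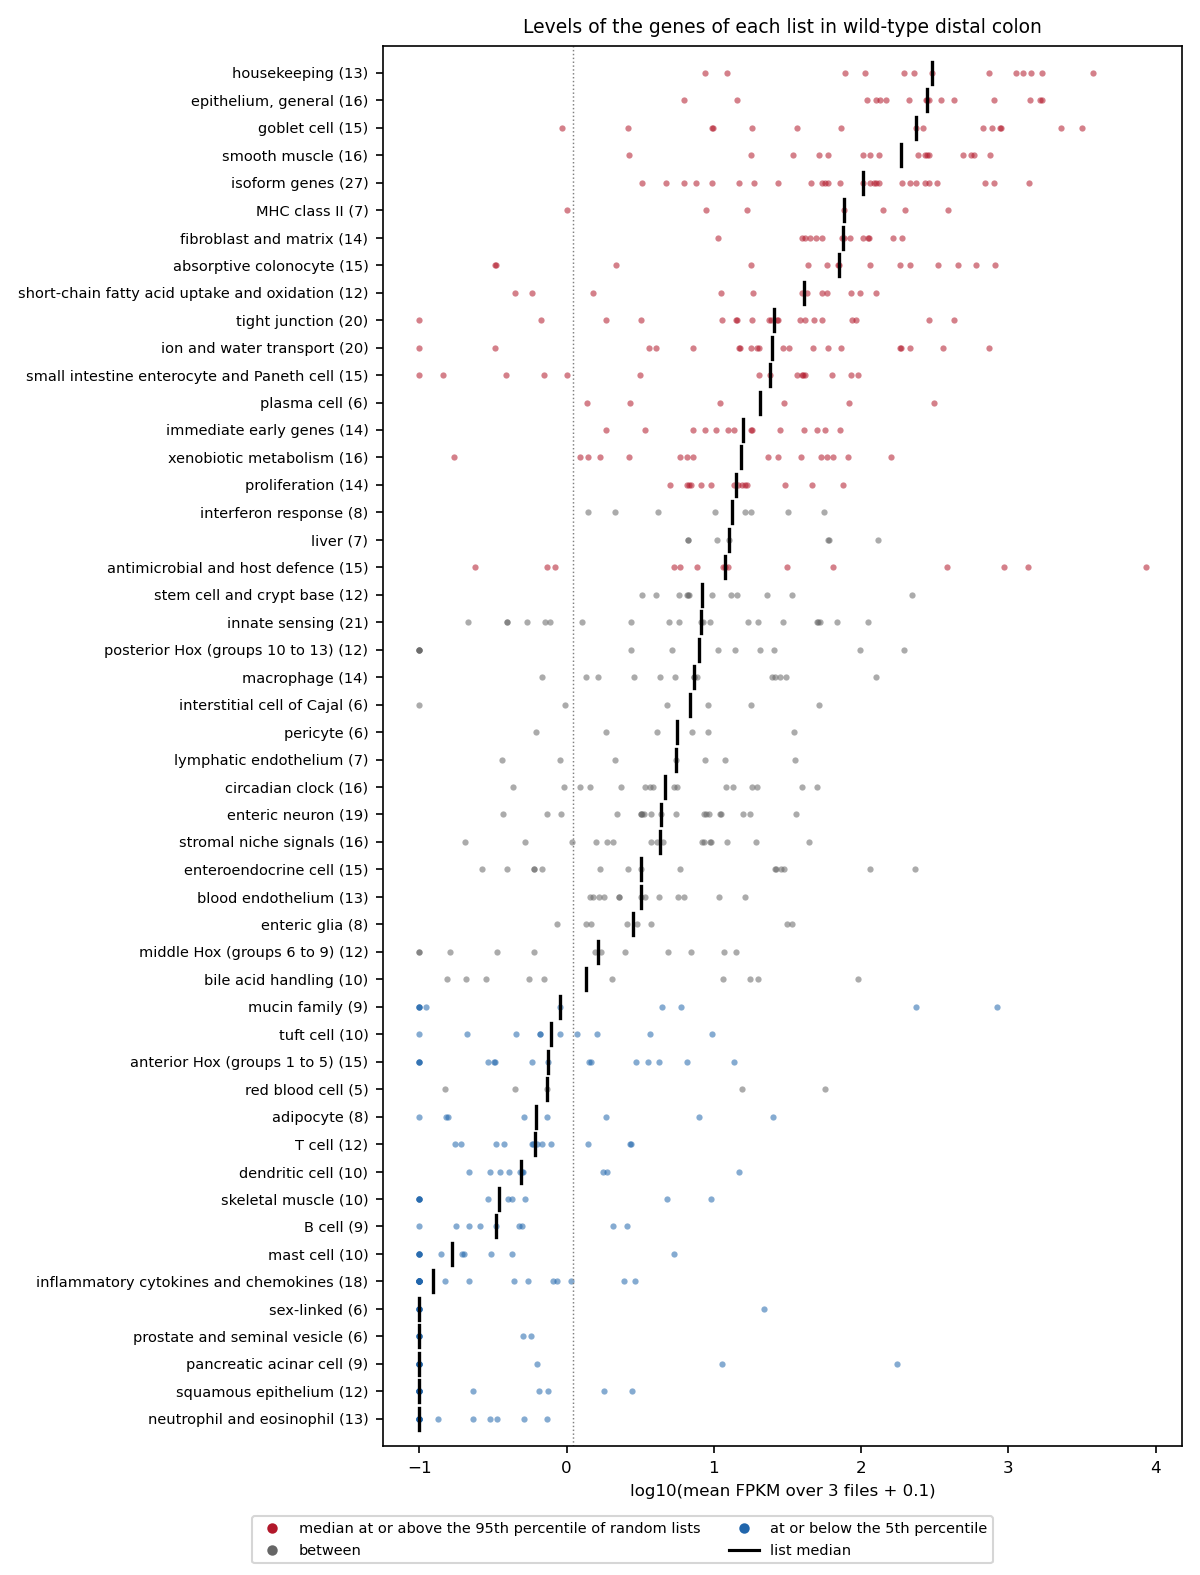
Each point is the mean level of 1 gene over the 3 files, as log10(FPKM + 0.1), in the list named at the left with its number of measured genes; black bars mark list medians, colours mark the percentile of the median among random lists of the same size, and the dotted line marks 1 FPKM. Epithelial, goblet cell and smooth muscle lists lie to the right, and lymphocyte, mast cell and granulocyte lists to the left.

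By the same rule as for the highest genes, the levels of further list genes are uncertain because a shorter stretch, from 2.13% (Muc4) to 25.3% (Tagln) of the transcript, matches another gene. These are Abcb1a, Atp1b1, Bhlhe40, Cd3e, Col3a1, Cxcl10, Grem1, Lrig1, Muc13, Nr1d1, Pigr, Ptgs1, Pycard and Zfp36 beside Muc4 and Tagln.

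The percentiles depend on the background, also in lists that passed neither the 5th nor the 95th. Clock genes lay at the 5.09th percentile against genes at or above 1 FPKM alone and at the 88.2nd against all genes listed. Pericyte genes lay at the 20.1st and the 79.9th in these 2 settings. Against genes at or above 1 FPKM alone, 5 lists left the upper range, namely proliferation (88.3rd percentile), plasma cell (90th), antimicrobial and host defence (77.9th), xenobiotic metabolism (93.1st) and immediate early genes (92.8th). A further 8 lists fell to the 5th percentile or under, namely enteroendocrine (0.640th), stromal niche (3.45th), blood endothelium (1.1th), enteric neuron (2.35th), enteric glia (1.28th), red blood cell (0th), bile acid handling (0th) and Hox genes of groups 6 to 9 (0.01th). Other settings moved these lists both ways. By the mean log2(FPKM + 1), blood endothelium genes fell from the 27.1st percentile to the 17.9th. Hox genes of groups 6 to 9 fell from the 6.69th to the 1.72nd by that mean. Against all genes listed, enteroendocrine genes lay at the 77.2nd percentile, stromal niche genes at the 86.4th, blood endothelium genes at the 75.5th, enteric neuron genes at the 88.5th and enteric glia genes at the 63.6th, and by the mean log2(FPKM + 1) enteroendocrine genes lay at the 70.8th. Against all genes listed, those at 0 included, 9 lists left the lower range, namely T cell (27.2nd percentile), B cell (23.1st), dendritic cell (24.1st), mast cell (9.68th), tuft cell (32.3rd), adipocyte (28.3rd), skeletal muscle (18.6th), mucin (41.4th) and Hox genes of groups 1 to 5 (35th). In that setting 6 lists entered the upper range, namely stem cell (96.3rd percentile), macrophage (95.5th), liver (96.8th), interferon response (97.8th), innate sensing (99th) and Hox genes of groups 10 to 13 (95.8th). The antimicrobial list fell to the 94.9th percentile without replicate 2 and to the 93.7th without replicate 3. The small intestine list fell to the 88.2nd when ranked by its mean log2(FPKM + 0.1).

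Hox genes mark the position along the body axis, and those of groups 10 to 13 are active in its hindmost part. Of the summed Hox FPKM, 82.5% ± 0.742 lay in groups 10 to 13, 9.71% ± 0.215 in groups 6 to 9 and 7.77% ± 0.559 in groups 1 to 5. Hoxb13 alone stood at 195 ± 0.610 FPKM (chromosome 11, 96194361 to 96196599) and Hoxd13 at 97.9 ± 2.29 FPKM (chromosome 2, 74668310 to 74671599). They were followed by Hoxa10 (25.7 ± 0.931 FPKM), Hoxd10 (20.4 ± 4.46 FPKM), Hoxd11 (13.8 ± 0.359 FPKM), Hoxa13 (10.6 ± 1.55 FPKM), Hoxd12 (5.12 ± 0.115 FPKM) and Hoxa11 (2.62 ± 1.05 FPKM). In groups 6 to 9, Hoxb9 (14.1 ± 0.294 FPKM) and Hoxa9 (11.6 ± 1.17 FPKM) stood above Hoxa7 (6.89 ± 1.42 FPKM), Hoxa6 (4.80 ± 0.563 FPKM), Hoxd9 (2.37 ± 0.633 FPKM), Hoxd8 (1.62 ± 0.363 FPKM) and Hoxb6 (1.45 ± 0.710 FPKM). In groups 1 to 5, Hoxa5 reached 13.6 ± 1.43 FPKM, Hoxa3 6.43 ± 1.35 FPKM, Hoxb5 4.14 ± 0.489 FPKM, Hoxa2 3.46 ± 0.575 FPKM, Hoxb2 2.84 ± 1.38 FPKM, Hoxb4 1.36 ± 0.276 FPKM and Hoxb3 1.32 ± 0.278 FPKM. Of the 9 Hoxc genes, 7 were listed at 0 in every file and the highest, Hoxc4, stood at 0.486 ± 0.221 FPKM. Of the 22 Hox genes with a mean of 1 FPKM or more, 9 share a stretch of at least 100 bases with a transcript of another gene (Hoxa2, Hoxa3, Hoxa7, Hoxa11, Hoxb2, Hoxb3, Hoxb5, Hoxd10 and Hoxd11), so their levels are uncertain, and the use of strand in the counting is not given in the sources used here.

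**Figure D2:**
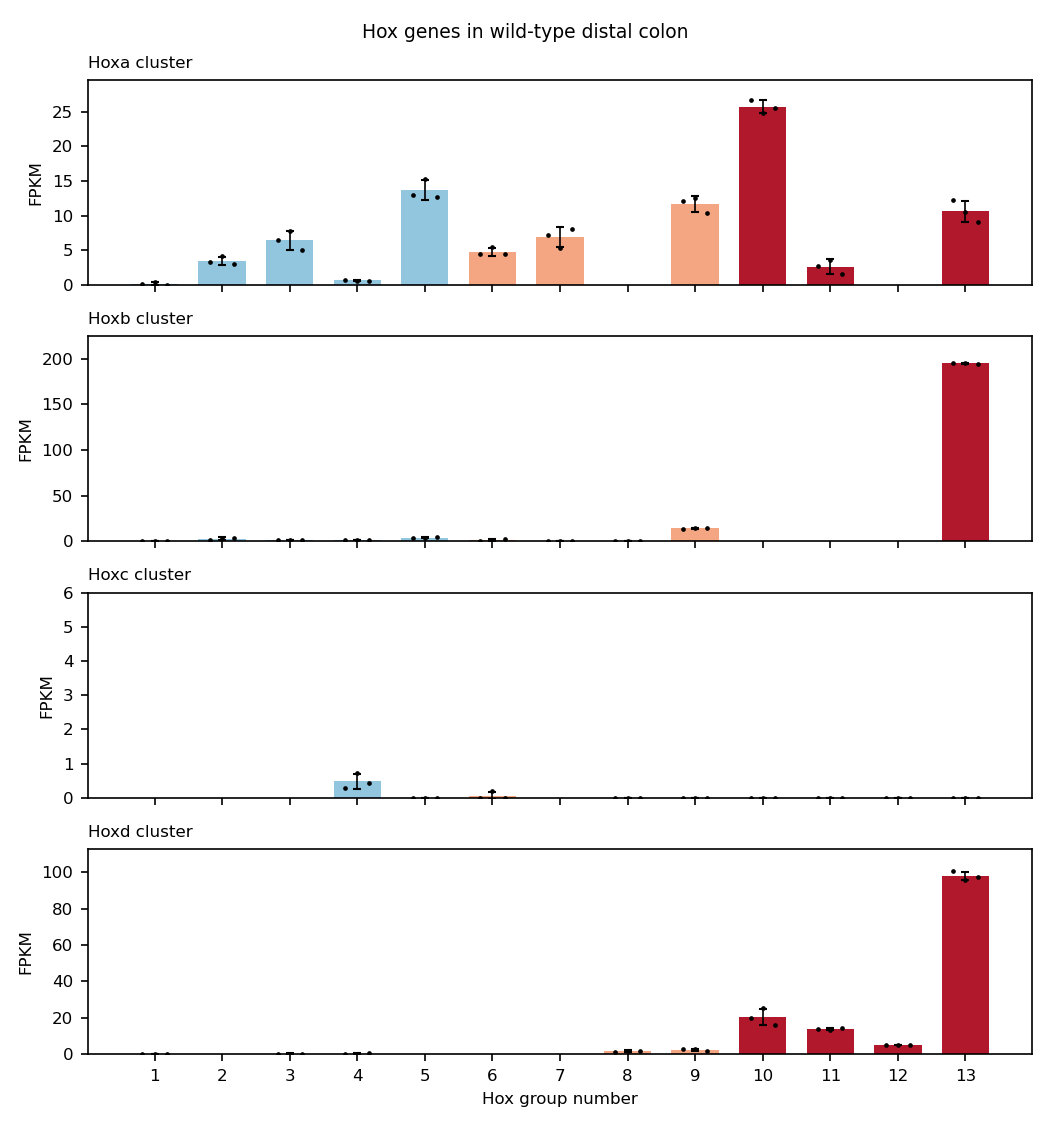
Bars give the mean FPKM of each Hox gene by group number, 1 panel per cluster and each panel with its own linear axis, error bars the SD over the 3 files and dots the 3 files; blue marks groups 1 to 5, orange groups 6 to 9 and red groups 10 to 13. Hoxb13 at 195 FPKM and Hoxd13 at 97.9 FPKM exceed every other Hox gene.

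The files give levels per RefSeq isoform. Of 3850 genes with 2 or more isoforms and a mean of at least 1 FPKM, 1150 (29.9%) held 90% or more of their FPKM in 1 isoform, and 549 of 1755 (31.3%) did so among genes at 10 FPKM or more. At the threshold of 1 FPKM the share was 35.3%, 35.4% and 34.3% without replicates 1, 2 and 3, higher than in the mean of all 3 files. Among contractile genes, the tropomyosin gene Tpm1 held 79.2% ± 0.593 of its FPKM in NM_001164249, and Tpm2 96.8% ± 0.520 in NM_001277876. The smooth muscle myosin gene Myh11 held 70.3% ± 5.99 in NM_001161775 against 29.7% ± 5.99 in NM_013607, the filamin gene Flna held 77.7% ± 8.69 in NM_010227 and Smtn 74.4% ± 2.98 in NM_001284427. Pkm, the pyruvate kinase gene, held 84.3% ± 1.90 in NM_011099 and 15.7% ± 1.90 in NM_001253883. Fn1 held 68.5% ± 5.41 in NM_001276410, Cd44 91.0% ± 3.72 in NM_001039151, Tpm3 93.2% ± 3.73 in NM_001253738, Cdc42 97% ± 0.560 in NM_009861 and the catenin gene Ctnnd1 74.2% ± 6.85 in NM_001085449. Rpl38, Gnas, Tpm3, Ctnnd1, Cox4i1, Txnip, Smtn and Fn1 are uncertain for transcripts of other genes that match them. The fibroblast growth factor receptor gene Fgfr2 held 70.4% ± 12.4 in NM_201601 and Tjp1 57.3% ± 13.7 in NM_009386, although replicate 3 placed NM_001163574 of Tjp1 higher, at 14.8 against 13.7 FPKM. Nnt, a mitochondrial transhydrogenase gene, had 7.42 ± 1.29 FPKM in the form listed as non-coding, NR_003544, which made 99.99% ± 0.0108 of its level. That share alone does not show a choice of isoform in the colon, and its cause was not tested. Cald1, Vcl, Hnf4a, Epcam, Myl6, Cdx2, Muc2, Slc26a3, Mylk, Actn1 and Cftr are each listed with 1 isoform.

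In 327 genes at 10 FPKM or more, at least 2 isoforms each held 20% or more in every file. The highest of these was Rpl38, split between NM_023372 (50.1% ± 8.56) and NM_001048058 (38.3% ± 13.2), with the second higher in replicate 1, at 574 against 552 FPKM. The cell adhesion gene Ceacam1 held 64.2% ± 0.431 in NM_001039186 and 31.0% ± 1.45 in NM_001039187, and the galectin gene Lgals3 73.0% ± 1.32 in NM_001145953 and 27.0% ± 1.32 in NM_010705. Gnas divided among NR_003258 (33.4% ± 1.58), NM_201616 (33.2% ± 7.5) and NM_001077510 (33.0% ± 7.51), which differed by less than the SD between files. The first-listed form exceeded the other in Cd74 (75.8% ± 2.84 in NM_010545, 24.2% ± 2.84 in NM_001042605), Txnip (62.9% ± 1.75 in NM_001009935, 37.1% ± 1.75 in NM_023719), Ly6a (73.8% ± 4.17 in NM_001271419, 23.3% ± 4.09 in NM_010738), Fhl1 (59.8% ± 3.22 in NM_001287800, 32.2% ± 3.16 in NM_001077362) and Atp5g3 (74.7% ± 3.82 in NM_175015, 23.2% ± 3.29 in NM_001301721). Cox4i1 showed 55.8% ± 7.98 in NM_001293559 in the mean, but replicate 3 alone placed NM_009941 higher, at 354 against 310 FPKM. Ptprc could not be divided at this depth: NM_001268286 held from 0.0372% to 99.9% of it in single files.

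**Figure D3:**
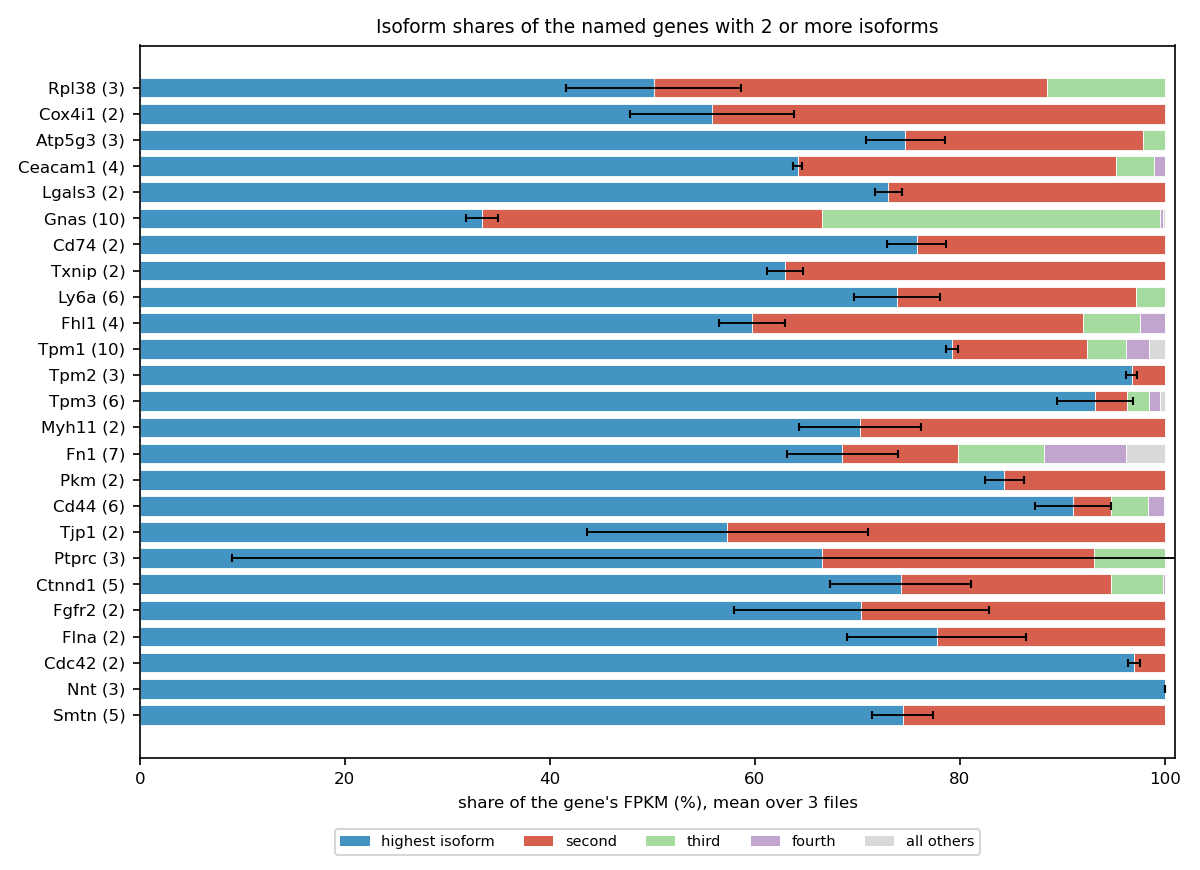
Stacked bars give the mean share of each gene's FPKM, in percent, held by its isoforms in order of level, with the number of listed isoforms in parentheses; the error bar is the SD of the highest isoform's share over the 3 files. Tpm2 and Cdc42 hold nearly all of their level in 1 isoform, Gnas divides among 3, and the bar of Ptprc has the widest error.

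The 3 files were compared with one another to find how far they vary. Among 8782 genes with a single isoform and a mean of at least 1 FPKM, 5 differed between the files by more than sampling noise (chi-square test on the variances implied by the confidence bounds, Benjamini-Hochberg adjusted). Among them were Sprr2a2 (adjusted p 3.05e-46), Sprr2a1 (2.82e-28), Gm5424 (2.68e-05) and Sprr2a3 (0.000261). In replicates 1, 2 and 3, Gm5424 stood at 8.45, 22.6 and 34.7 FPKM and Sprr2a2 at 1855, 1633 and 1886 FPKM. The next smallest p-values at 10 FPKM or more belonged to Lyrm2, BC002163, Idh3a, Nt5c and Sfr1, whose adjusted p lay between 0.0667 and 0.254 over all genes tested. In Benjamini-Hochberg adjustment over genes at 10 FPKM or more alone, Lyrm2 (0.0298) and BC002163 (0.0321) also passed. The count was 2 without replicate 1, 3 without replicate 2 and 5 without replicate 3. The median ratio of the variance between files to the sampling variance was 0.676 (bootstrap interval over genes 0.658 to 0.696), against 0.693 from noise alone, and 432 genes (4.92%) had an unadjusted p under 0.05. The median SD of log2(FPKM + 1) between the files was 0.14 and fell to 0.085 without replicate 3, the shallowest.

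**Figure D4:**
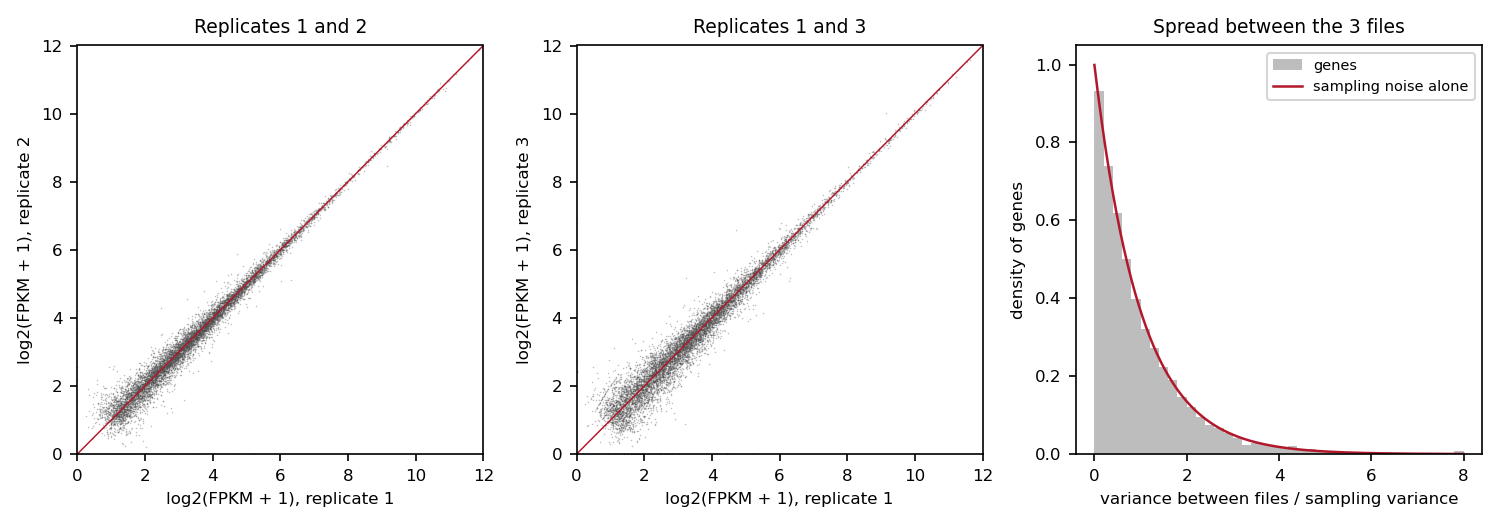
The left and middle panels plot log2(FPKM + 1) of the 8782 single-isoform genes in replicate 1 against replicates 2 and 3, with the line of equal levels in red. The right panel gives the distribution of the variance between files over the sampling variance (grey, values above 8 placed in the last bar) with the curve of sampling noise alone (red), which the genes follow.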

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

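Every alternative given here was fixed beforehand. The share of summed Hox FPKM in groups 10 to 13 moved by less than its SD in all 5 alternatives tried. The number of genes at 1 FPKM in every file stayed within 1.5 times of 11815 except at a threshold of 5 FPKM, which left 7779 by its construction. The 100 highest isoforms in place of genes held 30.3% of the summed FPKM, against 30.6%. The median SD of log2(FPKM + 1) between files, 0.14 as reported, was 0.15 with a pseudocount of 0.1, 0.16 with 0.01, 0.15 with no filter on low values, 0.095 in genes at 10 FPKM or more, 0.16 after rescaling each library to TPM, and between 0.085 and 0.12 with 1 replicate left out; the cause was not tested. The ratio of the spread between files to sampling noise was 0.624 when genes with several isoforms were included, and lay between 0.431 and 0.461 with 1 replicate left out, where noise alone gives 0.455. The number of genes that differ between files was 9 when genes with several isoforms were included and between 2 and 5 with 1 replicate left out; the cause was not tested. Restricting the isoform count to genes at 10 FPKM or more lowered it from 1150 to 549 because fewer genes were counted. Of 50 list percentiles under 8 alternatives, 214 of 400 values moved by less than the SD between files and 186 by more, and 29 lists changed side of the 5th or 95th percentile in at least 1 alternative, 13 of them when the background was limited to genes at 1 FPKM or more. The restriction to isoforms of status OK removed nothing and tests nothing, and the share without mitochondrially encoded genes was not run because none is among the genes analysed here. Depth limits the low genes: at 8.81e+06 fragments over the 3 files, 3 fragments made 1.72 FPKM for the short S100a8 transcript.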

Other observations

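Of the tests given here, that of 1 library divided into files of equal read number was chosen after the result was seen, and the others were set before their values were computed. The gene lists of these tests were written after the fixed lists had been read, when 2 of their genes (Cck and Muc5ac) had been seen. The sex-linked list gave 1 clear pattern. Xist, the RNA that coats the inactive X chromosome, stood at 22.0 ± 0.533 FPKM (chromosome X, 103460373 to 103483233), and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in every file, with limits of 0.0766, 0.216, 0.0645 and 0.0676 FPKM. Tsix, the antisense partner that shares 1982 bases with Xist, was listed at 0, and reads of the pair cannot be assigned without strand.

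Few genes of neighbouring tissues reached a mean of 1 FPKM. Squamous epithelium genes, which would mark anal skin, had a median below all random lists, with Krt10 at 1.70 ± 0.410 FPKM, and Krt5 at 0.132 ± 0.229 FPKM. Prostate and seminal vesicle genes had 0 of 6 members at a mean of 1 FPKM. The Y-linked genes listed at 0 argue against male tissue, so this absence cannot show whether neighbouring tissue was left out. Skeletal muscle genes had 2 of 10 at that mean, Ckm (uncertain for a match to another gene) at 9.40 ± 2.59 FPKM and Acta1 at 4.67 ± 1.57 FPKM. Adipocyte genes lay under the 5th percentile, or at the 28.3rd against all genes listed, with Fabp4 at 25.1 ± 7.56 FPKM and Adipoq at 0.416 ± 0.382 FPKM. Red blood cell genes lay at the 6.45th percentile, at the 4.84th without replicate 2 and at the 4.12th without replicate 3, but at the 31.1st by their mean log2(FPKM + 1) and at the 40.7th against all genes listed. Hba-a1 and Hba-a2, near-identical copies, stood at 34.0, 9.35 and 2.93 FPKM and at 39.1, 58.5 and 71.5 FPKM in the 3 files. Of the pancreatic acinar genes, 6 of 9 were listed at 0, but 2 reached a mean of 10 FPKM or more. These were Clps and the elastase gene Cela1, the latter at 175 ± 6.57 FPKM (chromosome 15, 100674422 to 100687920). In the lists of other organs, the lung secretory gene Scgb1a1 stood at 50.3 ± 7.97 FPKM and the surfactant gene Sftpc at 7.74 ± 2.39 FPKM. Of the 10 lung genes listed, 8 were under a mean of 1 FPKM, though none was at 0 in every file.

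The 3 files spread about as much as sampling noise. Over 7 lists that vary between animals or dissections, such as the clock, immediate early and plasma cell lists, the median ratio was 0.818. It came from the 42 of their 86 genes that were tested, and it argues against 3 separate animals. The squamous, adipocyte and skeletal muscle lists had only 2, 3 and 2 genes at a mean of 1 FPKM and so weigh little in it. The power of this test in the 42 genes was not simulated. The median ratio of 0.676 over all single-isoform genes is consistent with parts of 1 sequenced library. Replicates 1 and 2 differed by 0.147% in mapped fragments, and replicate 3 held 1.24e+06, which is consistent with 1 stream of reads divided into files of equal size with a remainder. The names of the 3 files carry the same sample, index and lane and differ only in the last number. Whether 1 library was sequenced more than once, or 1 RNA made into several libraries, was not tested, and neither was any biological explanation.

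Of 27 further abundant liver genes, none of them in another list, 88.9% had a mean of 1 FPKM or more, led by Serpina3k at 17.5 ± 0.593 FPKM, against 10.6% of 66 genes of kidney, lung, testis, heart, brain and stomach, so RNA or reads from liver are a candidate source. Their levels were low, with a median of 2.90 FPKM at the 15.6th percentile of random lists. Of 11 further Paneth cell genes 54.5% reached that mean (5.88th percentile, Defa3, uncertain for its near-identical copy Defa23, at 38.0 ± 8.69 FPKM), and of 13 further enterocyte genes 53.8% (3.34th percentile, Mep1b at 27.6 ± 3.36 FPKM), none of either in another list. Both shares lie between the bounds set for and against the small intestine as a source, and they are near that of all genes, of which 12632 of 24406 had such a mean, which keeps it open. How many genes of these lists the colon itself transcribes could not be read from these files, so origin in the colon stays open and no biological explanation was tested.

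Near-identical copies may account for the genes that differed between the files. At 10 FPKM or more, 7 genes passed the threshold, and 6 of them, or 85.7%, had a transcript of another gene that matched over at least 100 bases at 97% identity or more. Sprr2a1, Sprr2a2 and Sprr2a3 matched one another, Gm5424 matched Ass1 and BC002163 matched Ndufs5, while Lyrm2 had none. Of 298 random genes at that level 32.6% had such a match, above the 30% set beforehand as the limit for a clear contrast. The search counted overlapping genes as well, so this share is not that of near-identical copies alone. For that reason, and with 7 genes, the test leaves the explanation open.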
